A study of Mus musculus with 13 samples.

How the data were processed

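Genomic DNA of 13 mouse cerebellum libraries was sequenced to read copy number along the autosomes. Per the labels' protocols, DNA was extracted from formalin-fixed, paraffin-embedded sections with a Covaris truXTRAC kit and purified on magnetic beads, and libraries were made with an Illumina Nextera Flex kit. The tissue arose with aberrant Shh signalling in 7 libraries (genotype code BPtchD) and with aberrant Wnt signalling in 6 (codes BDCP and BCP), at a time point given as p30+. The codes, and the site codes PN and CB of the BPtchD tumours, are not spelled out in the labels and are used as given. Titles carry a specimen number: 3 PN and 3 CB libraries share the numbers 1382, 18576 and 35314, and there are 3 BDCP tumours (3, Black 3 and TQ 16) and 2 BCP tumours (2086 and 47177).

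A pair of libraries (BPtchD 1382 and BCP 47177) is titled Normal and shares its numbers with tumours. The series' design text describes this pair instead as tumours without any loss of Ddx3x. Both descriptions are kept in view: the pair entered no group comparison and served as the background measured the same way.

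The authors deposited sequencing read counts per bin of 100 kb, as whole numbers without normalization, for 24032 bins of the 19 autosomes. The authors also deposited smoothed log2 copy number values for 22707 of these bins, in which every library has a median of 0, and segmented log2 values that are constant along runs of bins. Bins with counts alone numbered 1325. The build is mm10, per the submitters' processing notes. The aligner, the counter, the correction behind the smoothed values and the segmentation method are not given in the sources used here. From the values, a segment was the mean of its smoothed bins plus a shift of the whole library, which ran from -0.08 (BDCP Black 3) to 0.064 (CB 18576).

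Libraries held 26699839 to 53901251 reads, a median of 1048 to 2097 reads per bin. Counting error alone gave a bin a log2 SD of 0.0315 to 0.0446, and neighbouring bins differed by a noise SD of 0.0608 to 0.124. Intervals and counting errors cover bin noise within a library only, since reads carry no molecular identifiers. A log2 threshold of 0.15 is reached when 1 extra copy is present in 21.9% of the cells, or 1 copy is lost from 19.7%.

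The percent of the genome altered was the percent of bins whose segmented value lay at least 0.15 from 0, and breakpoints were places within a chromosome where the segmented value changed. Both were compared by two-sided exact permutation tests. A chromosome of a library was called gained or lost when its median smoothed value was at least 0.15 from 0 and its 95% interval, from 2000 block bootstrap resamples of 5 Mb blocks, excluded 0. Chromosome medians, mean values of 2386 windows of 1 Mb and mean values of the bins over listed genes were tested between groups with limma 3.58.1, with Benjamini-Hochberg adjustment and a threshold of adjusted p = 0.05. In the comparison of Shh with Wnt tumours, each of the 3 Shh specimens was the mean of its PN and CB library, against 5 Wnt specimens. The similarity of PN and CB profiles was the mean Pearson correlation over windows, tested over the 6 pairings.

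Gene positions came from the gene table of assembly GRCm38.p6, the assembly of build mm10. The 10 gene lists held 165 symbols: Shh pathway, Wnt pathway, oncogenes amplified in medulloblastoma, tumour suppressors of medulloblastoma, chromatin regulators mutated in medulloblastoma, PI3K pathway, granule neuron lineage, Hox clusters, inflammasome and pyroptosis, and spindle checkpoint and centrosome. Of these, 156 were measured. The other symbols were 7 genes on X, 1 symbol outside the gene table and 1 autosomal gene without a copy number bin. Genes were named by a fixed rule: Ddx3x, Ptch1 and Ctnnb1 always, then up to 25 listed genes past the threshold, or, where none passed, the 25 lying in called segments in the most tumours. Chromosomes were named when called in at least 2 tumours. The 10 focal segments named were those of at least 5 bins with the largest values in a tumour and under 0.15 from 0 in both libraries titled Normal. Groups, tests, thresholds, lists and naming rules were fixed before the data were examined. Alterations of at least 10 Mb, with gaps of up to 1 Mb bridged, and the Skint and protocadherin regions were added after the data were seen.

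Alternatives were call thresholds of 0.1 and 0.3, segmented values, recentring of each library, windows of 5 Mb or single bins, the profile of the Normal libraries subtracted, PN or CB libraries alone, the specimen number as a block, and each library left out in turn. Count models were run on reads summed per window or chromosome: edgeR 4.0.16 with TMM or RLE factors and DESeq2 1.42.0. A filter at a mean count of 10 removed no window, so it decided nothing. Further alternatives, chosen after seeing the data, left out the 4 tumour libraries whose log2 values spread more widely within chromosomes than those of both Normal libraries, regressed out the Normal profiles, or exchanged the CB libraries numbered 18576 and 35314. The alternatives of the listed and named genes were also chosen then. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.

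The tests were tried on simulated data in which 200 of 2386 windows (2413 for edgeR) were changed by known amounts. Simulated windows were drawn independently of each other, unlike those of the real libraries. The limma data took the spread of each window, and the edgeR data a single median dispersion for all windows. The shares recovered by limma and by edgeR therefore cannot be compared with each other. For PN against CB, limma recovered 33.8% of windows changed by log2 0.15, 53.7% of those changed by 0.3 and 82.3% of those changed by the log2 ratio of 3 copies to 2. For Shh against Wnt tumours the shares were 4.35%, 48.6% and 88.1%. For BDCP against BCP tumours limma recovered 0.0% at every size, while edgeR, on 2413 windows, recovered 0.0%, 17.2% and 88.0%. For the other comparisons edgeR recovered 1.61%, 14.7% and 84.3% (PN against CB) and 4.17%, 37.0% and 96.3% (Shh against Wnt).

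The sex chromosomes hold no bin in these tables, so Ddx3x, which lies on X, was not analysed here. GC content was not analysed here, since no genome sequence was used.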

Results

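Copy number was read from 13 low-depth whole-genome libraries of mouse cerebellum: 3 BPtchD tumours from site PN, 3 from site CB, 3 BDCP tumours, 2 BCP tumours and 2 libraries titled Normal. The BPtchD tumours arose with aberrant Shh signalling and the BDCP and BCP tumours with aberrant Wnt signalling. Depth was 31980105 to 50440995 reads in the PN libraries, 26699839 to 48642121 in the CB libraries, 38077458 to 50480863 in the BDCP libraries and 38221220 to 40840604 in the BCP libraries. The Normal libraries held 53901251 reads (BPtchD 1382) and 48437538 reads (BCP 47177). The labels do not say that specimens came from separate animals, so p-values measure only the spread between these samples, which may be technical.

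Called chromosome medians in the 11 tumours were gains, 10 among 209 chromosome values, with 0 losses. Chromosome 15 was gained in 3 of the 5 Wnt tumours and in 0 of the 6 Shh libraries. Its median log2 ratio was 0.48 (95% interval 0.45 to 0.51) in BDCP 3, 0.34 (0.32 to 0.37) in BDCP TQ 16 and 0.27 (0.24 to 0.30) in BCP 2086. These ratios are what 1 extra copy in 78.2%, 53.5% and 41.2% of the cells would give, and 99.0% of the chromosome's windows lay above 0 in BDCP 3. The gained chromosome carries Myc, a growth-promoting transcription factor, Rictor, a subunit of the mTOR complex that phosphorylates AKT, and Rad21, a cohesin subunit. In BCP 2086 the median of chromosome 18 was also called (0.21, interval 0.14 to 0.25), through a gain of part of the chromosome.

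Chromosomes 7 and 19 were called at lower values, and only in libraries with wide regional spread. Chromosome 7 had medians of 0.15 in PN 35314, 0.17 in BCP 47177 and 0.17 in BDCP Black 3, and 0.15 in BCP 47177 Normal, the 1 call among 38 chromosome values of the Normal libraries. Chromosome 19 had medians of 0.19 in PN 35314, 0.18 in CB 18576 and 0.18 in BDCP Black 3. The SD of log2 values within chromosomes was 0.19 to 0.26 in these 4 tumour libraries (PN 35314, CB 18576, BCP 47177 and BDCP Black 3), 0.19 in BCP 47177 Normal and 0.060 to 0.15 in the other libraries. Without these 4 tumours, a setting chosen after seeing the data, 4 chromosome gains remained, those of chromosomes 15 and 18. Recentring each library gave 15 gains, and segmented medians gave 8 gains and 5 losses.

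**Figure D1:**
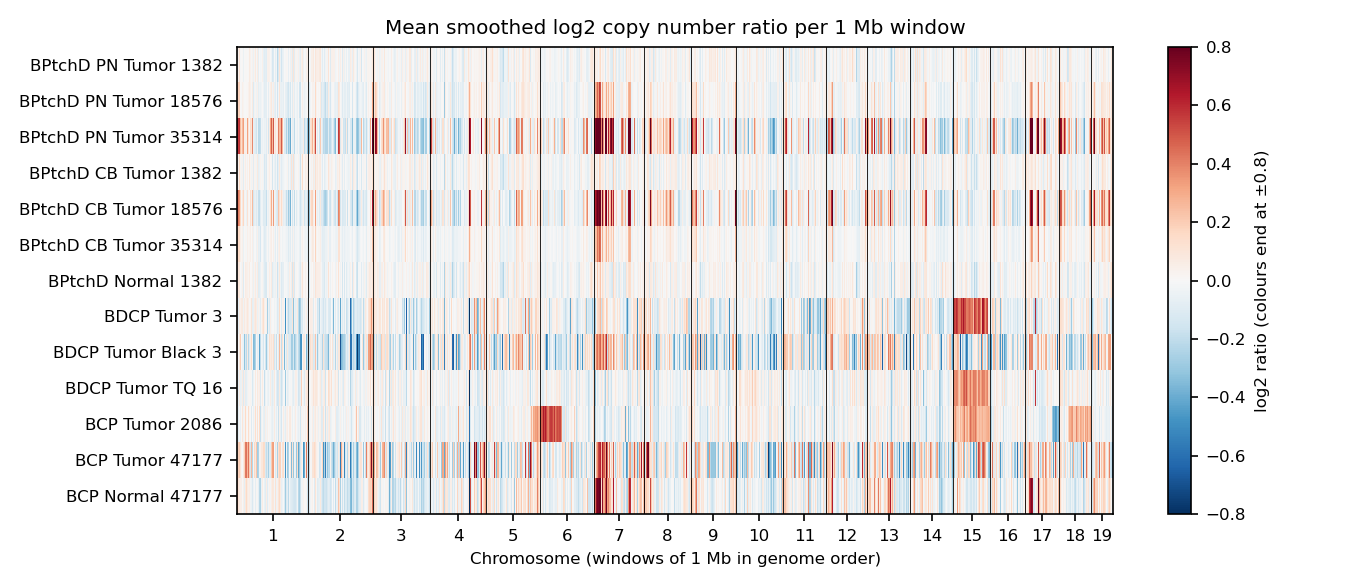
Mean smoothed log2 ratio of each 1 Mb window (colour, ending at 0.8 on either side of 0) along the 19 autosomes (x axis) in each of the 13 libraries (y axis). Chromosome 15 stands out in BDCP 3, BDCP TQ 16 and BCP 2086, and the start of chromosome 6 in BCP 2086 (median 0.51).

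**Figure D2:**
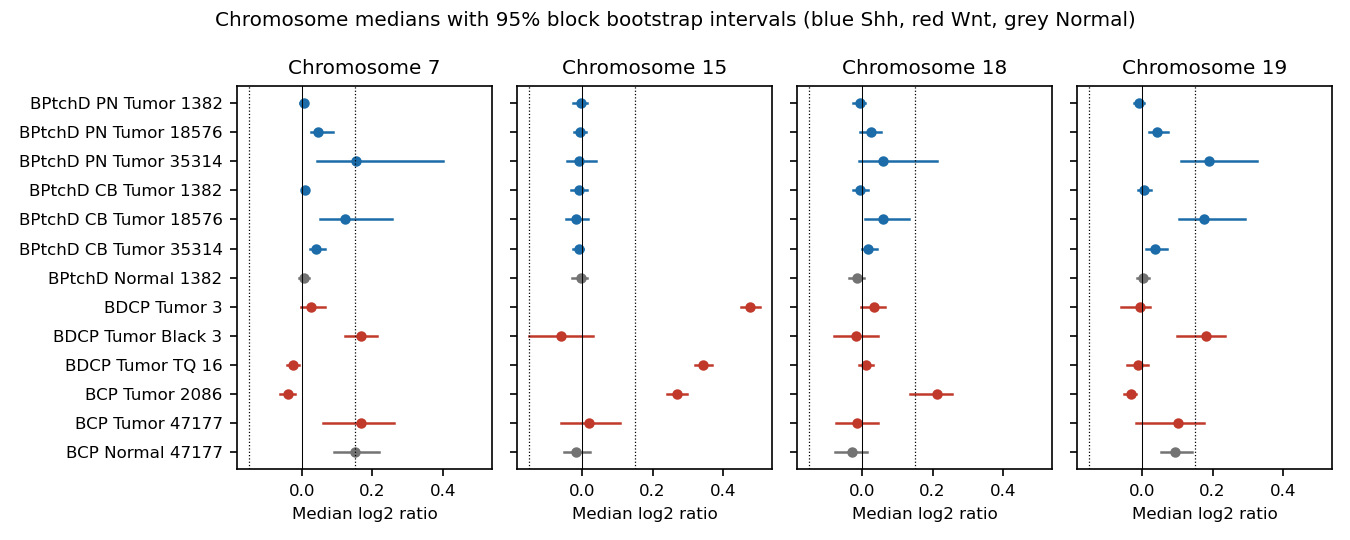
Median log2 ratio (x axis) of chromosomes 7, 15, 18 and 19 in each library (y axis), with 95% block bootstrap intervals as bars and dotted lines at 0.15 on either side of 0; blue is Shh, red Wnt and grey Normal. On chromosome 15 the gained libraries lie at 0.27 to 0.48.

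The comparison of PN with CB tumours asked whether BPtchD tumours of these sites differ in copy number. Chromosome medians were close: chromosome 15 lay at -0.0047 ± 0.0040 in PN and -0.011 ± 0.0047 in CB (SD, n = 3 each), a difference of 0.0060 (SE 0.0077; 95% interval -0.013 to 0.025). Chromosome 7 differed by 0.012 (interval -0.10 to 0.13) and chromosome 19 by 0.0033 (interval -0.16 to 0.16). Esco1, a cohesin acetyltransferase gene on chromosome 18, and Cdon, a hedgehog co-receptor gene on chromosome 9, lay in gained segments in the same 4 libraries, PN and CB of numbers 18576 and 35314, and in neither library of number 1382. Esco1 averaged 0.34 ± 0.20 in PN and 0.27 ± 0.11 in CB (SD, n = 3 each; limma adjusted p = 0.997 over the list alone). Cdon was also gained in the BCP 47177 tumour and called in BCP 47177 Normal.

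By limma, 0 of 19 chromosomes, 0 of 2386 windows and 0 of 156 listed genes differed between PN and CB at adjusted p = 0.05. At an unadjusted p under 0.05 there were 0 chromosomes, 2 windows against 119 expected by chance, and 0 genes. The counts by edgeR (chromosomes and windows) and DESeq2 (windows) were also 0. The altered part of the genome was 14.3% ± 18.9 in PN and 10.3% ± 13.6 in CB (SD, n = 3 each; two-sided exact permutation p = 0.6, smallest possible 0.1). Breakpoints numbered 176.7 ± 196.8 and 157.0 ± 168.4 (SD, n = 3 each; exact permutation p = 0.9). Each group held 1 library with wide regional spread, PN 35314 with 35.8% altered and CB 18576 with 25.8%, while the other 4 libraries ranged from 0.352% to 6.35%. The difference in the altered part, 4.02 percentage points, became -6.76 without PN 35314 and -0.94 without CB 1382. The difference in breakpoints, 19.7, became -93.5 without PN 35314, -51.3 without CB 1382 and -2.33 without CB 35314.

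PN and CB libraries with the same number had a mean correlation of 0.856 over windows, which are not independent replicates, against a mean of 0.661 over the 6 pairings (exact permutation p = 0.5, smallest possible 0.167). The highest correlations joined different numbers: 0.955 for PN 35314 with CB 18576, and 0.917 for PN 18576 with CB 35314. The same-number values were 0.865 (1382), 0.863 (18576) and 0.84 (35314). BPtchD 1382 Normal correlated about as highly with the tumours of its number, at 0.874 with CB and 0.857 with PN. For 1382 the correlation is thus not particular to tumours. With the mean of the Normal libraries subtracted, the same-number mean was 0.607, against 0.547 over the 6 pairings.

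The comparison of BDCP with BCP tumours asked whether these genotypes differ within Wnt tumours. BCP 2086 carried long alterations of several chromosomes. The start of chromosome 6 (3400001 to 61900000) was gained at a median of 0.51, a copy ratio of 1.43, while the rest of the chromosome lay at -0.033. This segment holds 409 protein-coding genes, among them Smo, the signal transducer of the hedgehog pathway, the receptor tyrosine kinase gene Met, Gsdme and the Hoxa cluster. The same tumour gained chromosome 18 from 26700001 to 90600000 (0.26), which holds the Wnt pathway inhibitor gene Apc and the kinase gene Csnk1a1, and the end of chromosome 5 from 129500001 to 151700000 (0.27), which holds Brca2. It lost the end of chromosome 17 from 77300001 to 94900000 (-0.35). None of these 4 segments overlapped an alteration of at least 10 Mb in the same direction in another library, but the loss of 28200001 to 43300000 on chromosome 8 (-0.20) overlapped such losses in BCP 47177 and BDCP Black 3. The segments were chosen after their values were seen.

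**Figure D3:**
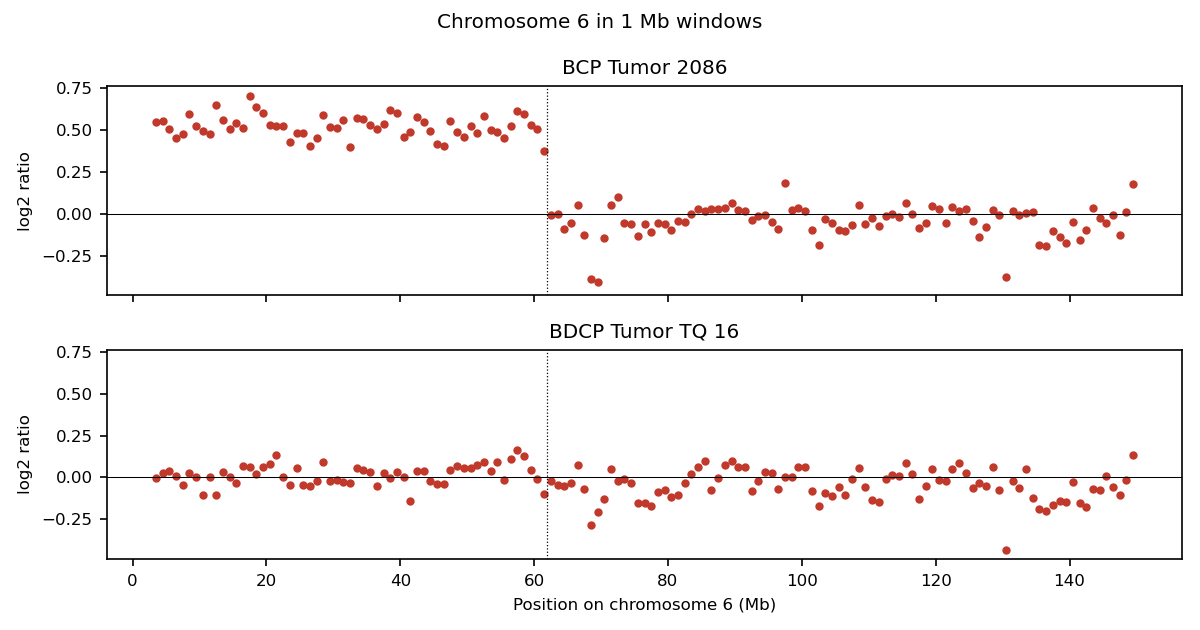
Mean smoothed log2 ratio (y axis) of each 1 Mb window along chromosome 6 (x axis, Mb) in BCP 2086 (top) and, for reference, BDCP TQ 16 (bottom); points are windows and the dotted line marks the end of the gained segment. In BCP 2086 the median falls from 0.51 before the line to -0.033 after it.

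BDCP 3 showed losses, such as -0.29 at 55900001 to 67200000 of chromosome 9, which overlapped losses of at least 10 Mb in BCP 47177 and BDCP Black 3, and -0.21 at 23700001 to 36100000 of chromosome 17, the part with Tsc2 and Axin1. Lrp6, a Wnt co-receptor gene, lay in a lost segment at the end of chromosome 6 in both BDCP 3 and BDCP TQ 16. Chromosome 15 averaged 0.25 ± 0.28 in BDCP (SD, n = 3) and 0.15 ± 0.18 in BCP (SD, n = 2), a difference of 0.11 (SE 0.17; limma adjusted p = 0.993). Gsdme, which encodes a pore-forming effector of pyroptosis, averaged 0.032 ± 0.080 in BDCP (n = 3) and 0.40 ± 0.23 in BCP (n = 2), a difference of -0.37 (SE 0.15; limma adjusted p = 0.988 over the list alone).

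By limma, 0 chromosomes, 0 windows and 0 listed genes differed between BDCP and BCP tumours at adjusted p = 0.05. At an unadjusted p under 0.05 there were 0 chromosomes, 23 windows against 119 expected by chance, and 1 gene, Gsdme; edgeR and DESeq2 passed 0 windows as well, with 15 and 40 at an unadjusted p under 0.05. The altered part of the genome was 26.2% ± 20.9 in BDCP (SD, n = 3) and 29.8% ± 21.0 in BCP (SD, n = 2; two-sided exact permutation p = 0.8, smallest possible 0.1). Breakpoints numbered 287.0 ± 136.0 and 261.5 ± 231.2 (exact permutation p = 0.8). The difference in the altered part, -3.64 percentage points, became 5.03 without BDCP TQ 16 and 11.2 without BCP 47177, and that in breakpoints, 25.5, became -43.0 without BDCP Black 3 and -138 without BCP 2086. Without BDCP Black 3 and BCP 47177, the libraries with wide spread, 78 windows passed, 58 of them on chromosome 6, and 10 listed genes, with BCP then the single tumour 2086, assumed to vary like BDCP.

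The comparison of Shh with Wnt tumours asked whether the signalling type goes with different copy number. Chromosome 15 lay at -0.0077 ± 0.0032 in the Shh specimens (SD, n = 3) and at 0.21 ± 0.22 in the Wnt tumours (SD, n = 5). The difference was -0.22 (SE 0.11; 95% interval -0.48 to 0.043), and it did not pass (limma adjusted p = 0.908; edgeR log2 fold -0.24, adjusted p = 0.17). A two-sided exact permutation test gave p = 0.214 (n = 3 and 5, smallest possible 0.018), and Fisher's exact test of 3 gained among 5 against 0 among 3 gave p = 0.196; both were chosen after the values were seen. Myc averaged -0.18 ± 0.034 in Shh (n = 3) and 0.27 ± 0.30 in Wnt tumours (n = 5), a difference of -0.45 (SE 0.15; limma adjusted p = 0.277 over the list alone and 0.616 over all bins). Part of this difference is a low value in Shh of the bins over Myc alone, since the chromosome lay at -0.0077 there. Myc lay in a called segment in 0 Shh libraries. Without the libraries with wide spread the difference of chromosome 15 was -0.37 (SE 0.049; limma adjusted p = 0.00423, against up to 0.999 in the other alternatives), but this setting removed exactly the Wnt tumours in which chromosome 15 was not gained.

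Some listed genes were called lost more often in Wnt tumours, though none passed in the test between the groups. Trp53, together with its neighbours Ctdnep1, Nlrp1a and Aurkb on chromosome 11, lay in lost segments in 4 of 5 Wnt tumours, all but BCP 2086, and in 0 of 6 Shh libraries and 0 Normal libraries. Trp53, the gene of the p53 protein that halts damaged cells, averaged -0.35 ± 0.20 in Wnt tumours (n = 5) and -0.075 ± 0.088 in Shh (n = 3; difference 0.28, SE 0.11; limma adjusted p = 0.431 over the list alone). Arid1a, a subunit gene of the SWI/SNF chromatin remodeller, was lost in the same 4 Wnt tumours, down to -0.61 in BDCP 3. It averaged -0.54 ± 0.32 in Wnt tumours (n = 5) and -0.063 ± 0.017 in Shh (n = 3; difference 0.48, SE 0.16; limma adjusted p = 0.277 over the list alone), and it was also called in BCP 47177 Normal at -0.34. The inflammasome genes Pycard and Aim2 were lost in 4 Wnt tumours and called in 1 Normal library each. Of the 4 tumours with these losses, 2 were libraries with wide regional spread. BDCP 3 was not among these, but over windows it correlated at 0.54 with BCP 47177 and 0.471 with BCP 47177 Normal. It may thus carry part of the wide pattern too. For BDCP TQ 16 these correlations were 0.207 and 0.242.

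By limma, 0 chromosomes, 0 windows and 0 of 156 listed genes differed between Shh and Wnt tumours at adjusted p = 0.05, over the list alone or over all bins. At an unadjusted p under 0.05 there were 0 chromosomes, 180 windows against 119 expected by chance, and 17 genes against 7.8. By edgeR, 0 chromosomes passed, with 4 at an unadjusted p under 0.05, and 2 windows passed, both on chromosome 12 and higher in Shh; by DESeq2, 158 windows passed, 135 higher and 23 lower. At an unadjusted p under 0.05 there were 517 windows by edgeR and 597 by DESeq2, against 121 expected by chance. The altered part of the genome was 12.3% ± 10.4 in Shh specimens (SD, n = 3) and 27.6% ± 18.2 in Wnt tumours (SD, n = 5; two-sided exact permutation p = 0.25, smallest possible 0.018). Breakpoints numbered 166.8 ± 120.3 and 276.8 ± 151.0 (exact permutation p = 0.321). Measured the same way, BCP 47177 Normal had 23.3% altered and 281 breakpoints, near the means of the Wnt tumours. The BPtchD Normal library had 1.08% and 28. These measures therefore do not separate tumour changes from the wide regional pattern. The altered part also rests on segmented values, which were shifted by -0.08 in BDCP Black 3 (49.4% altered) and by 0.064 in CB 18576 (25.8%). With the CB libraries numbered 18576 and 35314 exchanged, an alternative chosen after seeing the data, the SDs of the Shh specimens rose to 16.3 and 182 (exact permutation p = 0.321 each).

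The first of the edgeR windows, at 22000001 to 23000000 of chromosome 12, held predicted genes such as Gm10476 and Gm9295. It has no copy number value and was not tested by limma. Its read count, scaled to the library total (CPM), was 29.8 to 53.5 in Shh specimens and 5.34 to 10.3 in Wnt tumours (log2 fold 2.35; edgeR adjusted p = 0.00904). The BPtchD Normal library, at 32.2, lay with the Shh specimens and the BCP Normal library, at 9.87, with the Wnt tumours. The other window, at 113000001 to 114000000, holds the immunoglobulin heavy chain locus with 39 Ighv genes (log2 fold 0.63; edgeR adjusted p = 0.0369; limma adjusted p = 0.717). Here both Normal libraries, at 502 (BPtchD) and 474 (BCP), lay within the range of the Shh specimens, 472 to 601, and above that of the Wnt tumours, 323 to 420.

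Across the gene lists, none of the 10 had a member past the threshold in any comparison, adjusted over the list alone or over all bins. In the comparison of Shh with Wnt tumours, all 15 measured genes of the Hox clusters, on 4 chromosomes, had lower values in Shh (median difference -0.15), with 4 at an unadjusted p under 0.05. Hoxa5 differed by -0.41 (SE 0.11; limma adjusted p = 0.277 over the list alone). Of 19 Wnt pathway genes, 16 had higher values in Shh (median difference 0.12), with Csnk2b and Lrp6 at an unadjusted p under 0.05. Of 14 Shh pathway genes, 11 were higher in Shh (0.086; Sufu), and of 16 tumour suppressors 13 (0.094; Trp53 and Tsc2). The chromatin regulators had 11 of 15 higher in Shh (0.063; Smarca4, Arid1a and Ncor1) and the PI3K pathway 11 of 14 (0.092; Pik3ca and Tsc2). The granule neuron lineage had 2 of 13 higher (-0.12; 0 at an unadjusted p under 0.05) and the oncogenes 8 of 22 (-0.040; Myc). The inflammasome list had 11 of 16 higher (0.037; Gsdmd and Zbp1) and the spindle list 9 of 15 (0.048; Esco1). Genes on 1 segment are not independent of each other.

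For PN against CB the lists' median differences stayed between -0.024 (Wnt pathway) and 0.011 (PI3K pathway), and for BDCP against BCP between -0.10 (chromatin regulators) and 0.037 (oncogenes).

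Of the 156 listed genes, 143 lay in a called segment in at least 1 tumour, so such calls were common. Of the 25 named by frequency, 11 were also called in a Normal library, 6 lie on chromosome 15, and 17 were called in at least 2 of the 7 tumour libraries without wide spread. Rictor (chromosome 15, 6708349 to 6800401) led with 6 tumours, gained in 5, up to 0.54 in BDCP 3, and lost in BCP 47177 at -0.27. Rad21 (15, 51962604 to 51993538) was gained in 3 and lost in 2 Wnt tumours, and Myc (15, 61985341 to 61990361) was gained in 3, up to 0.51 in BDCP 3, and lost in 1. Smo (6, 29735497 to 29761366) was gained at 0.52 in BCP 2086 and lost in 3 Wnt tumours. Zbp1, a sensor of nucleic acids, was gained in 5 tumours, and Tert and Mycn in the 4 tumours with wide regional spread; each of these genes was also called in 1 Normal library.

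The loci of Ptch1 and Ctnnb1 were examined at the resolution of a bin. Ptch1 (chromosome 13, 63508328 to 63573460), the receptor gene that restrains hedgehog signalling, is overlapped by 1 bin with a copy number value. Its value minus that of the flanking 1 Mb averaged -0.12 ± 0.11 over the 6 Shh tumour libraries (SD), from -0.27 in PN 35314 to 0.024 in PN 1382, with 0.045 in the BPtchD and -0.090 in the BCP Normal library. Against a flank of 3 Mb the mean was -0.20, and the Normal libraries lay at -0.027 and -0.14. The bin itself averaged -0.073 ± 0.076 over the 6 Shh tumour libraries (SD). It lay at 0.028 in PN 35314 and 0.001 in CB 18576, so their low differences came from a raised flank. In the 5 Wnt tumours the difference ran from 0.006 to 0.214 against the flanking 1 Mb, and from -0.11 to 0.241 against 3 Mb. The segment over Ptch1 was gained in PN 35314 (0.52), CB 18576 (0.44) and BDCP Black 3, lost in CB 1382 (-0.19), and called in both Normal libraries. Ctnnb1 (chromosome 9, 120933400 to 120960507), which encodes beta-catenin, averaged 0.019 ± 0.035 over the 5 Wnt tumours (SD), or -0.039 ± 0.048 minus the flanking 1 Mb, and lay in a called segment in 0 tumours. Ddx3x was not analysed here.

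Among focal segments, the largest value was 1.16 at 30400001 to 31000000 of chromosome 17 in BDCP 3, with a matching segment of 1.01 at 30400001 to 30900000 in BDCP TQ 16. Both hold Btbd9, Dnah8 and Glo1, the gene of the methylglyoxal-detoxifying enzyme glyoxalase, and the Normal libraries lay at 0.023 and 0.065 there. Neither Normal library carries the code BDCP, so they cannot tell an inherited variant from a gain in the tumour. The median smoothed value over 30400001 to 30900000 was also raised in BCP 47177, at 0.33. It was 0.039 in BDCP Black 3 and -0.052 in BCP 2086. BDCP Black 3 had losses of -0.87 on chromosome 2 (138000001 to 139600000; Btbd3 and Sptlc3), -0.86 on chromosome 3 (Negr1), -0.82 on chromosome 10 (Btg1), -0.82 on chromosome 13 (Pde4d and Plk2) and -0.81 on chromosome 4 (Tlr4 and Brinp1). BCP 47177 lost a segment of chromosome 13 with the PI3K subunit gene Pik3r1 (-0.82) and gained one of chromosome 4 with Grik3 (0.81). BDCP Black 3 and BCP 47177 are libraries with wide regional spread. The lost segments of BDCP Black 3 were called in 4 tumours in all on chromosomes 2, 10 and 13, in 3 on chromosome 4 and in 2 on chromosome 3. BCP 47177 Normal lay at -0.13 over that of chromosome 2 and -0.149 over that of chromosome 10, and at -0.088 to -0.042 over the others. BDCP 3 gained 83600001 to 84700000 of chromosome 15 further, to 0.81, a segment with 12 protein-coding genes.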

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

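In this part the test of gene family windows was chosen before its result was seen, and the tests of depth, of copy number changes and of exchanged numbers only after it.

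Among 66 sets of values examined for a library far from the others, 9 held one, against 3.3 expected by chance, which picks about 1 in 20. Some sets picked after their values were seen are not among the 66, such as chromosome 18 and the start of chromosome 6, which was delimited by the gain in BCP 2086 itself. All 9 are sets of named genes. Apart from Ctnnb1, these genes were named by how often their segmented values were called in these tumours. They were thus picked from the values examined here, so the rate of 1 in 20 does not hold for them and the counts decide nothing about chance. Among the Wnt tumours, BCP 2086 lay apart with a chromosome 18 median of 0.212 (others -0.017 to 0.033) and a median of 0.512 over the start of chromosome 6 (others -0.099 to 0.026). In the same group the kinase gene Akt2 lay at 0.399 in BCP 47177 (others -0.010 to 0.064). Among the Shh libraries, CB 18576 lay apart at -0.046 over the start of chromosome 6, at 0.222 for the mitotic kinase gene Aurka and at 0.095 for Ctnnb1. PN 35314 lay apart at -0.058 for Smo, 0.199 for the Wnt co-receptor gene Lrp5, 0.246 for Shh, -0.094 for Aim2, and -0.050 for both Hoxc4 and Hoxc5, which share a segment. For Ctnnb1 the other Shh libraries lay at 0.018 to 0.031, for Aurka at -0.082 to 0.012, for Shh at 0.006 to 0.076 and for Lrp5 at -0.005 to 0.070.

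The share of the genome altered, minus that of the Normal library of the same number, was -0.418 percentage points in PN 1382, -0.727 in CB 1382 and 21.3 in BCP 47177. All libraries numbered 1382 had at most 1.08% altered, so their differences are close to 0. Both libraries numbered 47177 have wide regional spread (44.7% altered in the tumour and 23.3% in the Normal library). The difference between these signalling types was not tested. Reads in the bins without copy number values, which entered the count models but no limma test, took 4.14% of the library in PN 35314, 3.66% in CB 18576 and 3.25% in BCP 47177, against at most 3.2% in the Normal libraries.

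PN 35314 and CB 18576, which carry different numbers, shared a regional pattern with a correlation of 0.955 over windows. Low depth is argued against as its cause, since their spread within chromosomes was at least 16.7 times the counting error of a window, and copy number changes of a single animal or its tumour as the whole cause are argued against by correlations of at least 0.57 with BCP 47177 Normal. Recovery of olfactory, vomeronasal and zinc finger gene clusters that differs between libraries is a candidate explanation for part of it: the 94 windows with at least 5 such genes lay 0.407 (95% interval 0.137 to 0.596) above the other 2292 in CB 18576 and 0.547 (0.186 to 0.698) above them in PN 35314, against -0.0075 to 0.235 in the other libraries. Specimen numbers 18576 and 35314 exchanged at 1 site cannot be told apart from a shared technical pattern, because at fine scale PN 35314 correlated better with CB 18576 (0.689) than with CB 35314 (0.38), but PN 18576 about equally with CB 35314 (0.523) and CB 18576 (0.548). No biological difference named by the design was tested for this pattern.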

How the results depend on the processing

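Of the alternatives below, those without the 4 tumour libraries of wide regional spread, with the Normal profiles regressed out, with CB numbers exchanged, and those of listed genes were chosen after seeing the data. Over 19 results that answer a comparison, 185 alternatives stayed the same, while 2 were weaker, 9 stronger and 10 reversed. Over the other results 102 stayed, while 45 were weaker, 1 stronger and 6 reversed. For a difference, the same meant its direction and side of the threshold, and for a count an equal or similar number. Counts of passing chromosomes, windows and listed genes were 0 in the main setting, and most of their alternatives gave 0 again. Such counts have no direction to keep, so they say little about robustness. Without the 4 libraries of wide spread, limma passed 1 chromosome (15), 112 windows (34 higher and 78 lower in Shh, 76 of the lower on chromosome 15) and 9 listed genes for Shh against Wnt tumours, and 78 windows and 10 genes for BDCP against BCP; chromosome gains numbered 4, and the difference in breakpoints between PN and CB became -0.5. The gains of chromosome 15 explain that chromosome and its 76 windows by construction, because the Wnt tumours left were those that carry it, and proximal chromosome 6 of the only BCP tumour left explains 58 of the 78 windows; the cause of the rest was not tested. For windows of Shh against Wnt tumours, edgeR passed 2 with TMM, 2 with RLE factors and 2 without a filter, and DESeq2 passed 158; the cause was not tested. At a threshold of 0.3, 2 chromosome gains remained, both on chromosome 15. With CB libraries alone, the chromosome 7 difference of Shh against Wnt tumours, 0.00327, became -0.00273; the cause was not tested.

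With each library left out in turn, the differences ranged as follows. The altered part of the genome ran from -6.76 (without PN 35314) to 11.8 percentage points for PN against CB, negative also without CB 1382 (-0.94). It ran from -18.5 to 11.2 (without BCP 47177) for BDCP against BCP, positive also without BDCP TQ 16 (5.03), and from -20.1 to -9.48 for Shh against Wnt tumours. Breakpoints ran from -93.5 (without PN 35314) to 113 for PN against CB, negative also without CB 1382 (-51.3) and CB 35314 (-2.33), from -138 (without BCP 2086) to 189 for BDCP against BCP, negative also without BDCP Black 3 (-43.0), and from -156 to -41.8 for Shh against Wnt tumours. For Shh against Wnt tumours chromosome 15 ran from -0.285 to -0.151 and chromosome 19 from 0.0074 to 0.0649. Chromosome 7 ran from -0.0216 (without BCP 2086) to 0.0311, and was negative also without specimens 18576 (-0.00765), 35314 (-0.0137), BDCP 3 (-0.00483) and BDCP TQ 16 (-0.0178). Counts of chromosomes, windows and listed genes stayed at 0. The causes were not tested.

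With the specimen number as a block, PN against CB gave 0 chromosomes, 0 windows and 0 listed genes, so the block changed no call, and sign-flip tests gave 4.02 percentage points and 19.7 breakpoints (exact p = 0.75 each, n = 3). Deviations from the group means correlated at 0.936 for 1382, but at -0.815 for 18576 and -0.716 for 35314, so that not every library correlated best with its own number. Each group mean carries the pattern of its library with wide spread, PN 35314 or CB 18576. Among libraries without wide spread, PN and CB deviations correlated at 0.669 to 0.936, also across numbers. The signs thus follow from the wide pattern and cannot decide whether the numbers pair the libraries. On simulated BDCP and BCP data limma made no call and edgeR recovered 17.2% of the windows changed by 0.3, but the spread was simulated differently for each.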

Other observations

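In this part the test of chromosome 15 in uncorrected reads and the splits of listed genes were chosen before the results were seen, and the other tests only after.

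The Skint genes on chromosome 4 (112100001 to 113900000; 7 genes of a butyrophilin-like family expressed in skin and thymus) varied widely between the Wnt libraries. The median log2 ratio was -3.71 in BCP 47177, -3.19 in BCP 47177 Normal, -1.76 in BDCP TQ 16, -1.33 in BDCP 3, -0.72 in BCP 2086 and 0.28 in BDCP Black 3. In the BPtchD libraries it lay between 0.014 and 0.82. The clustered protocadherin genes on chromosome 18 (36800001 to 37800000; 54 cell adhesion genes of this family) lay at 0.94 in PN 35314, 0.78 in CB 18576, 0.55 in BCP 47177 and 0.44 in BCP 47177 Normal, and at 0.069 to 0.40 in the other libraries. BDCP 3 and BDCP TQ 16, which share the gain over Glo1, also shared a loss of 51000001 to 51600000 on chromosome 16 (-0.60 and -0.44), a segment with 0 protein-coding genes, where the Normal libraries lay at -0.041 and -0.050. Here too an inherited variant was not excluded, since neither Normal library carries the code BDCP.

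Alterations of at least 10 Mb numbered 10 in BDCP 3, 6 in BCP 2086, 3 in PN 18576, 2 in BDCP TQ 16, 1 in CB 35314, and 0 in PN 1382, CB 1382 and the BPtchD Normal library. Among the libraries with wide spread there were 26 in BDCP Black 3, 23 in BCP 47177, 17 in PN 35314, 13 in CB 18576 and 12 in BCP 47177 Normal. In BDCP 3 the lost parts included 93000001 to 110200000 of chromosome 10 (-0.22), 107800001 to 119100000 of chromosome 13 (-0.23) and 86200001 to 100400000 of chromosome 14 (-0.23). Each of these overlapped losses of at least 10 Mb in BCP 47177 and BDCP Black 3, those of chromosomes 10 and 14 also in PN 35314, and that of chromosome 14 in BCP 47177 Normal.

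Chromosome 15 was gained in BDCP 3, BDCP TQ 16 and BCP 2086. The authors' correction of the log2 values is argued against as the cause, because the share of uncorrected reads on chromosome 15, as log2 over its mean in the Normal libraries, was at least 0.268 in these libraries, against -0.0071 ± 0.037 (SD, n = 8) in the other tumour libraries. A regional bias of the kind seen in the 5 libraries with wide spread is argued against by their highest chromosome 15 median of 0.021. Wnt against Shh signalling cannot be told apart from a chance difference, because limma gave an adjusted p of 0.908 with 3 and 5 specimens. A gain of the chromosome in part of the cells of these libraries may therefore be a biological change, as a hypothesis found and tested on the same data. The share of tumour cells was not measured, so a gain in all tumour cells is not excluded.

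For the low Skint values of both libraries numbered 47177, a regional bias is argued against by a distance from 0 of at least 14.2 within-chromosome SDs, and reads that cannot be placed among near-identical copies by the lowest BPtchD median of 0.014. Loss of only 1 copy is argued against in both libraries, since their medians (-3.71 and -3.19) lie below -1.0, the log2 ratio of 1 copy to 2. Copy ratios of 0.0762 in BCP 47177 and 0.11 in its Normal library need both copies missing from most cells. An inherited variant of the animal cannot be told apart from such a loss in the tumour. The library titled Normal helps define the pattern and is tumour tissue by the series' design text. The lower but less extreme values in BDCP 3, BDCP TQ 16 and BCP 2086 were not tested.

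Other splits of the samples were counted for each count by limma. For PN against CB, the 10 splits of 6 libraries are too few for a share under 0.05: the real split passed 0 chromosomes, 0 windows and 0 listed genes, and the highest other split 0 of each. For Shh against Wnt tumours the real split passed 0 of each as well, so all 56 of 56 splits had to give as many, and the count decides nothing about chance. The highest other split passed 5 chromosomes when BDCP 3, BDCP TQ 16 and BCP 2086 were set against the rest, and 182 windows and 35 listed genes when BDCP 3, BDCP Black 3 and BCP 47177 were. Few of the 56 splits passed anything: 3 for chromosomes, 3 for windows and 2 for listed genes. The highest split for chromosomes set apart the 3 tumours that gained chromosome 15.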
